A study of Mus musculus with 24 samples.

How the data were processed

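RNA of mouse C3H 10T1/2 fibroblasts, polyadenylated per the labels but with much ribosomal sequence in wild type and clone 1, was measured in 24 libraries: wild type cells and 2 LncMyoD knockout clones, each untreated, given MyoD adenovirus, given LncMyoD plasmid or given both, with 2 libraries per group. Per the labels, cells grew in 10% fetal bovine serum, changed to 2% horse serum after transdifferentiation. Full-length cDNA was made with a low-input kit that does not mark strand and tagmented, and paired reads of 100 nt were sequenced, per the labels' protocols. The submitters' processing notes name bcl2fastq 2.19, Trimmomatic 0.36, HISAT2 2.1.0, SAMtools 1.3, StringTie 1.3.3 and the mm10 build, without saying how each was used. The file headers name StringTie 2.1.2, which differs from the notes, with the GENCODE vM21 annotation as guide and with assembly of unannotated transcripts switched on. Per the file headers the libraries of each line were numbered consecutively, which defines no library or sequencing batch.

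Each deposited file lists the transcripts assembled in 1 library. The authors' deposited values per transcript are coverage per base, which is not normalized, FPKM and TPM, and the main results use the TPM. TPM is a share within a library, so a transcript class that takes a large share lowers other values. TPM summed to no fixed total per file and was used as deposited; percents of TPM are of that sum. No read counts were used, and the ratio of deposited coverage to FPKM, which was constant within each file, put the depth at 2.43 to 5.92 gigabases of aligned fragments per library. The number of reads behind a value is unknown, so no counting interval is given.

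TPM was summed over the transcripts of each gene. A transcript without a reference gene was given to the gene that shared at least 50% of its exonic length on the same strand, and otherwise left out; these left-out transcripts held 8.53% to 39.0% of TPM per library, the most in clone 1 with MyoD replicate 1. All 35260 gene identifiers matched the vM21 annotation. A gene with no transcript in a file has the value 0, which can be a failed assembly. Gapdh, which all cells use, was at 1.07 to 30.8 TPM and Actb at 60.2 to 5701 TPM, so such genes can be assembled poorly, merged with neighbours or split with pseudogenes. Where a gene is listed at 0 in a whole group, the TPM of each library is given in the results of each comparison, and fitted values of such genes, given with the alternatives and the tests of differences, depend on the pseudocount. Genes at Lars2 and at the ribosomal repeat copy on chromosome 17 take reads of ribosomal type. Antisense and overlapping genes are uncertain because the kit does not mark strand.

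Genes with at least 1 TPM in at least 2 libraries were tested, 17886 in all. The test was limma 3.58.1 in R 4.3.3, with a mean-variance trend, on log2(TPM + 1) with 1 mean per group over all 24 libraries and 12 residual degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison and a log2 change of at least 1 in size. Log2 changes are on the log2(TPM + 1) scale, which understates changes of low genes. The 11 comparisons were MyoD against none in each of 3 lines, knockout (mean of both clones) against wild type without treatment and with MyoD, the plasmid alone and with MyoD in wild type and in the knockout lines, and 2 differences of such responses between knockout and wild type. Values of each clone stand beside the mean. The test of that mean uses the spread within groups, so the variation between clones does not enter its p-values. A call for the mean therefore holds for these clones and is no test of the genotype. The shift in the median of all genes is given with each count it concerns.

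Of 22 gene lists fixed beforehand, 18 with at least 5 measured members were tested with camera at a preset correlation of 0.01 and again with an estimated correlation. The adjusted p is over the 18 lists of a comparison. Counts of called members are given over all genes and adjusted over the list alone. List medians are over members, while camera compares members with the other genes.

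The text names Myod1, the transcripts within 60 kb of it at the LncMyoD locus, and Myog, Mef2c, Myh3, Acta1, Ckm, Mymk, Col1a1, Id1 and Mki67 where MyoD is involved. For each comparison it names up to 8 largest rises and 8 largest falls among calls whose replicates do not overlap and whose higher arm has a mean of at least 5 TPM, without predicted, ribosomal protein, small RNA and mitochondrial genes. In the interactions these had the same sign in both clones. For each list up to 4 called members with the largest change, of which up to 2 are given in the text, and members against the direction of the list were taken. Where a comparison had up to 7 calls, all are named, and those outside the rule were chosen after their values were seen.

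The alternatives were each clone alone, an estimated correlation, a filter of 5 TPM, no filter, a pseudocount of 0.1, the replicate number as a block, each library left out, only the groups that enter a comparison, FPKM, median-of-ratios scaling, quantile normalization, library quality weights, voom weights on reads estimated from coverage, and reference-named transcripts only. Added after seeing the data were TPM re-scaled over named nuclear genes outside the ribosomal window, exon coverage per gene, fits without the clone 2 libraries and fits of only those. Labels share replicate numbers across groups without saying that a number marks a batch, so no block is in the main design.

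The scripts were tested on simulated data with 17886 genes made from the real means, 100 genes changed by 1.5 and 100 by 3 on the log2 scale. For MyoD in wild type 44% and 94% were called, for MyoD in clone 2 39% and 94%, and for the difference in MyoD response 21% and 86%. Of 17656 unchanged genes 9, 9 and 6 were called. Parsing used Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6 and bedtools 2.31.1, and figures used matplotlib 3.10.9. Random steps used seed 1.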

Results

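RNA was profiled in C3H 10T1/2 cells, a mouse embryo fibroblast line that MyoD, a transcription factor, turns into muscle. The parent line (wild type) and 2 knockout clones of the long noncoding RNA LncMyoD were compared. Each line was untreated, infected with MyoD adenovirus, transfected with LncMyoD plasmid or given both, with 2 libraries per group. The comparisons ask what MyoD changes in each line, whether the knockout lines differ in that response, and what the plasmid adds. The labels do not say that the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. The labels describe a change of medium to 2% horse serum with transdifferentiation, so medium and MyoD may go together. No labelled group got an empty virus or plasmid, so each response includes any effect of infection or transfection.

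The files give TPM (transcript abundance as a share of a library) and no read counts. TPM summed to 810049 to 968266 per library in wild type, 710312 to 922352 in clone 1 and 956986 to 979898 in clone 2. The ratio of coverage to FPKM put the depth at 4.40 to 5.92 gigabases of aligned fragments per library in wild type, 2.43 to 5.10 in clone 1 and 3.49 to 5.04 in clone 2. Clone 2 stood apart from the other lines. A window of ribosomal RNA sequence (chromosome 17, 39841353 to 39853827) held 55.6% to 69.2% of all TPM in wild type, 36.8% to 69.99% in clone 1 and 2.68% to 7.89% in clone 2. Mitochondrial transcripts held 2.06% to 3.84%, 1.32% to 2.20% and 7.91% to 14.0% in the same order. Between 12985 and 14777 genes reached 1 TPM in the clone 2 libraries, against 7651 to 9930 in the others. Across genes, Pearson's r of log2(TPM + 1) was 0.918 to 0.939 between wild type libraries, 0.819 to 0.902 between wild type and clone 1, and 0.610 to 0.679 between wild type and clone 2. The labels give no batch. The file headers name the gene table in 1 way for all 8 clone 2 libraries and in another for the 16 others. They write a full directory for 5 clone 2 libraries and for none of the others, and the highest correlation with another line was 0.679 for these 5 and 0.677 for the other 3.

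**Figure D1:**
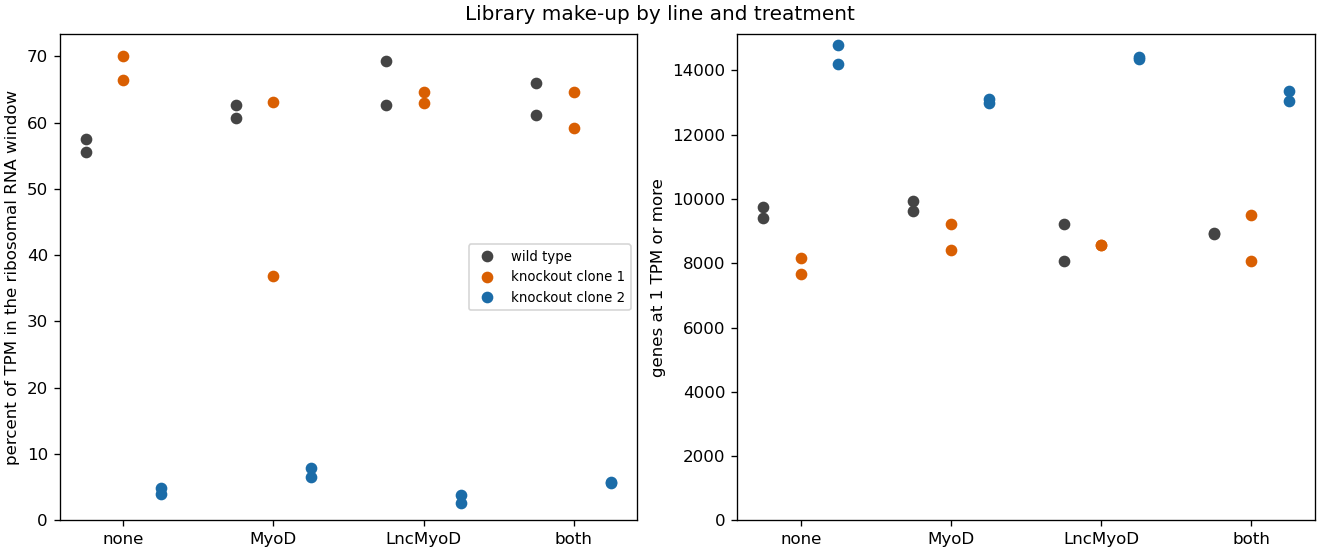
Percent of TPM in the ribosomal RNA window (left) and number of genes at 1 TPM or more (right), 1 point per library, by treatment and coloured by line. The 8 clone 2 libraries lie at 2.68% to 7.89% and at 12985 to 14777 genes, apart from the 16 others.

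The targeted locus and Myod1 were examined first as a check of the labels. Myod1 (chromosome 7, 46376474 to 46379099, build mm10) was listed at 3.23 and 3.23 TPM in untreated wild type and at 3571 and 3735 TPM with MyoD. The values were 2.44 and 3.76 TPM and then 1665 and 2328 TPM in clone 1, and 1.23 and 1.01 TPM and then 1163 and 929.6 TPM in clone 2. With MyoD and the plasmid they were 3301 and 3659 TPM in wild type, 2479 and 3641 TPM in clone 1 and 1220 and 1222 TPM in clone 2. Myod1 rose with MyoD in all 3 lines (limma adjusted p = 7.43e-12, 3.16e-11 and 3.07e-11 in the same order). These values do not separate the viral from the chromosomal gene. At the LncMyoD locus an unnamed minus-strand transcript of 2 exons and 621 nt (chromosome 7, 46345772 to 46351188) was assembled in 12 of 12 libraries given the plasmid and in 0 of the 12 others. It overlaps the annotated noncoding gene 1700025L06Rik (46345771 to 46349373). Its level was 2.64 to 8.16 TPM in wild type, 16.8 to 53.3 in clone 1 and 3.47 to 11.9 in clone 2. Since the wild type libraries without the plasmid also lacked it, with and without MyoD, the locus checks the plasmid labels and says nothing on the knockout labels.

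**Figure D2:**
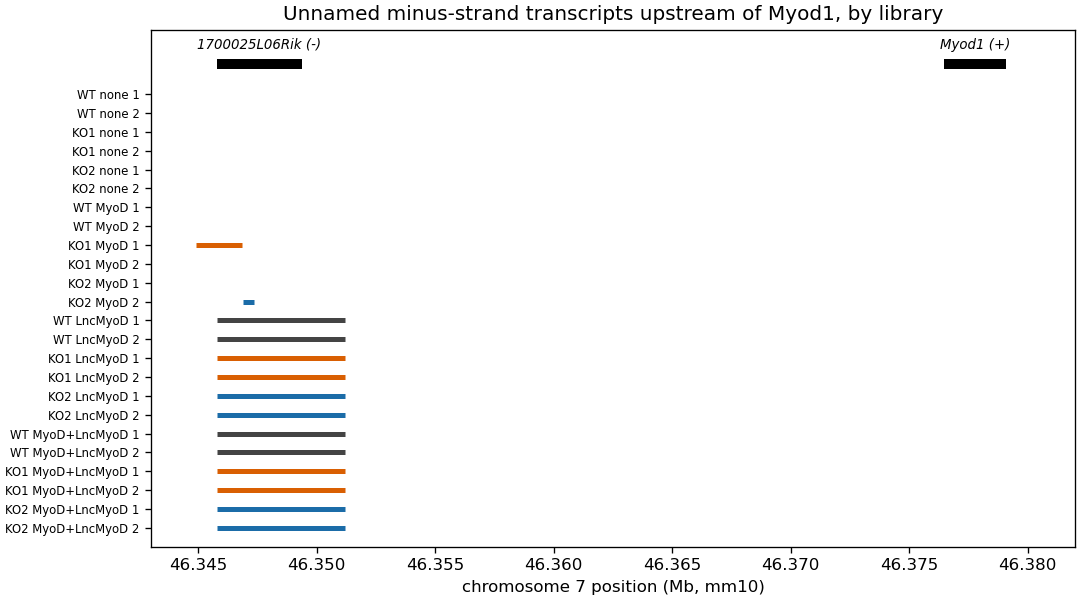
Unnamed minus-strand transcripts in each of the 24 libraries (1 line per library, coloured by line) along chromosome 7 (Mb, mm10), with the annotated genes 1700025L06Rik and Myod1 as black bars. The 2-exon transcript appears, drawn from its start to its end, in the 12 plasmid libraries and in 0 of the 12 others, where clone 1 with MyoD replicate 1 and clone 2 with MyoD replicate 2 hold shorter fragments at 0.692 and 1.95 TPM.

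In wild type cells contractile genes and a pair of neighbouring imprinted genes rose with MyoD. Igf2, a fetal growth factor (chromosome 7, 142650766 to 142666816), rose from 4.62 ± 3.27 TPM (SD, n = 2) to 328 ± 25 TPM (SD, n = 2), a log2 change of 6.0 ± 0.354 (SE). H19, a noncoding RNA beside it, rose from 0.874 ± 0.282 TPM (SD, n = 2) to 28.5 ± 0.747 TPM (SD, n = 2), and Cck, a peptide hormone gene, from 0.314 ± 0.443 TPM (SD, n = 2) to 8.19 ± 0.722 TPM (SD, n = 2). The cardiac and skeletal actins Actc1 and Acta1, the giant sarcomere protein gene Ttn, the fetal acetylcholine receptor subunit Chrng and the kinase gene Nmrk2 were listed at 0 in both untreated libraries. With MyoD, Actc1 was at 8.57 and 10.5 TPM, Acta1 at 4.25 and 6.93 TPM, Ttn at 6.07 and 11.2 TPM, Chrng at 6.02 and 11.2 TPM and Nmrk2 at 24 and 5.62 TPM, with limma adjusted p from 4.24e-05 to 0.0431. Lrch1 fell by 3.98 ± 0.67 (SE) on the log2 scale, but gave 0.26 when exon coverage per gene was used, and was at 0.843 and 11 TPM with the plasmid and 21.3 and 16.3 TPM with both.

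Of 32 measured sarcomere genes 3 rose and 0 fell in wild type, and 8 rose adjusted over the list alone (median log2 change 0.507, camera adjusted p = 3.38e-14). Of 16 myogenic regulators 0 rose over all genes and 4 rose adjusted over the list alone (median 0.427, camera adjusted p = 1.33e-06). Of 17 genes of excitation-contraction coupling and the neuromuscular junction 1 rose, and 4 rose adjusted over the list alone (median 0.441, camera adjusted p = 1.82e-07). Myog, the transcription factor myogenin, was at 0 TPM untreated and 5.05 and 3.82 TPM with MyoD (limma adjusted p = 0.13), and the fusion protein gene Mymk at 0 untreated and 4.65 and 2.53 TPM with MyoD (adjusted p = 0.194). Mef2c was at 0 untreated and 0.41 and 3 TPM with MyoD, and the muscle creatine kinase Ckm at 0 in all 4 libraries. Col1a1, Id1 and Mki67, genes of collagen, a MyoD inhibitor and proliferation, gave log2 changes of -0.18, -0.16 and 0.11 (adjusted p = 1 for each), and Myh3 did not pass the expression filter. Camera called none of the other 15 tested lists (adjusted p from 0.237 to 0.891). They were myoblast fusion, muscle energy metabolism, cell cycle, cell cycle exit, fibroblast and extracellular matrix, smooth muscle and TGF-beta response, bHLH inhibitors and Notch, interferon response, NF-kB inflammation, endoplasmic reticulum stress, p53 targets, cholesterol synthesis, immediate early, adipocyte, and cartilage and bone. Heart and macrophage had 3 measured members each (median log2 change 0.609 and 0), neuron had 4 (0) and epithelium 0, too few to test.

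Over all 17886 genes tested, limma called 21 in wild type, 17 higher and 4 lower. The count was 6 and 8 without untreated replicate 1 or 2, and 12 and 9 without MyoD replicate 1 or 2. It ran from 1 with only these groups in the fit to 74 with exon coverage per gene, and quantile normalization gave 24 higher and 10 lower.

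In knockout clone 1 the same imprinted genes rose with MyoD. The ribosomal RNA window held 69.99% and 66.4% of TPM untreated and 36.8% and 63.1% with MyoD. H19 was listed at 0 untreated and at 11.4 and 14.1 TPM with MyoD, and Igf2 rose from 2.78 ± 0.22 TPM (SD, n = 2) to 39.8 ± 12.4 TPM (SD, n = 2), a log2 change of 3.40 ± 0.354 (SE). Ttn was listed at 0 and then at 4.37 and 11.3 TPM (limma adjusted p = 0.0221). Numa1, a spindle protein gene, rose from 15.6 ± 2.34 TPM (SD, n = 2) to 62.2 ± 7.87 TPM (SD, n = 2), but its log2 change of 1.93 became -0.26 with exon coverage, -1.71 with reference-named transcripts only and -0.01 with voom weights. Of 32 sarcomere genes 1 rose and 0 fell, and 5 rose adjusted over the list alone (median 0.390, camera adjusted p = 0.000114). Of 17 excitation-contraction coupling genes 0 rose, and 3 rose adjusted over the list alone (median 0.712, camera adjusted p = 0.00512, or adjusted p = 0.0945 with an estimated correlation). Untreated clone 1 libraries had Acta1, Myog and Mymk at 0. With MyoD Acta1 was at 0.727 and 2.47 TPM (limma adjusted p = 0.318), Myog at 0 and 2.69 TPM and Mymk at 1.77 and 0.73 TPM, and the 3 did not pass. Ckm was at 0 in all 4 libraries. Mef2c, Col1a1, Id1 and Mki67 gave log2 changes of 0.89, 0.26, 0.28 and -0.07 without passing the test. Camera did not call the other 16 lists (adjusted p from 0.13 to 0.905).

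The limma test called 20 genes in clone 1, 20 higher and 0 lower, with 1438 genes in either direction at an unadjusted p under 0.05. The count was 7 and 6 without untreated replicate 1 or 2, 13 without MyoD replicate 1 and 497 without MyoD replicate 2. It ran from 0 with only these groups in the fit to 790 with exon coverage, and median-of-ratios scaling gave 144 higher and 72 lower.

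In knockout clone 2 muscle genes rose with MyoD and growth-response and matrix genes fell, while the makeup of the libraries moved too. Mitochondrial transcripts held 8.03% and 7.91% of TPM untreated and 13.3% and 14.0% with MyoD, the ribosomal RNA window 4.05% and 4.91% and then 6.61% and 7.89%, and 14777 and 14215 genes and then 12985 and 13106 reached 1 TPM. Mylpf, a fast muscle myosin light chain (chromosome 7, 127208890 to 127214298), was listed at 0 untreated and at 267 and 129 TPM with MyoD, and Myog at 0 and then 95.2 and 43.9 TPM. Troponin gene Tnnc2 rose from 0.616 ± 0.872 TPM (SD, n = 2) to 164 ± 93.9 TPM (SD, n = 2), Myl1 from 1.57 ± 2.22 TPM (SD, n = 2) to 174 ± 87.2 TPM (SD, n = 2), and Acta1 from 5.5 ± 1.42 TPM (SD, n = 2) to 168 ± 95.4 TPM (SD, n = 2). Cck and H19 rose by log2 changes of 6.36 ± 0.407 and 6.07 ± 0.324 (SE). Osgep, which makes a tRNA modification, rose by 5.97 ± 1.48, but its replicates in clone 2 were at 0.922 and 69.9 TPM with the plasmid and 0.207 and 85.6 TPM with both. Ckm was listed at 0 and then at 10.5 and 4.64 TPM, and Mymk rose from 0.818 ± 0.261 TPM (SD, n = 2) to 14.8 ± 11.8 TPM (SD, n = 2).

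Of 32 sarcomere genes 17 rose and 0 fell in clone 2, and 19 rose adjusted over the list alone (median 2.23, camera adjusted p = 1.71e-31). Of 17 excitation-contraction coupling genes 10 rose, and 11 adjusted over the list alone, with Chrng at 0 and then 18.7 and 16.4 TPM and the calcium channel subunit Cacng1 at 0 and then 12.4 and 11.1 TPM (camera adjusted p = 5.53e-17). Of 15 muscle energy genes 5 rose, over all genes and adjusted over the list alone, among them Pgam2 by 3.98 ± 0.966 (camera adjusted p = 6.53e-06). Of 16 myogenic regulators 3 rose and 1 fell, and 4 rose and 2 fell adjusted over the list alone, with Smyd1 at 0 and then 5.26 and 3.27 TPM. Camera placed that list above other genes (adjusted p = 0.00794) while its median was -0.0684 and its mean 0.416. Among fusion genes 3 of 15 rose and 3 fell, both over all genes and adjusted over the list alone, with Mymx up by 2.83 ± 0.453 (camera adjusted p = 0.817). Ankrd1, of the heart list, was at 0 and then at 21.9 and 12.2 TPM.

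Immediate early genes, which respond to growth factors within minutes, fell in 14 of 16 members, over all genes and adjusted over the list alone (median -2.42, camera adjusted p = 2.38e-19). Fosb, Egr2, Nr4a1 and Fos gave log2 changes of -4.77 ± 0.527, -4.37 ± 0.464, -4.38 ± 0.338 and -4.36 ± 0.375 (SE). Cell cycle genes fell in 12 of 37 members, and in 18 adjusted over the list alone (median -1.29, camera adjusted p = 1.44e-06), among them Ccna2 (-3.62 ± 0.585) and Ccnb2 (-2.4 ± 0.662), while Mki67 gave -1.03 ± 0.563 without passing. Endoplasmic reticulum stress genes fell in 9 of 16, also 9 adjusted over the list alone (median -1.38, camera adjusted p = 1.32e-06), with Atf3 at -2.78 ± 0.667 and Chac1 listed at 3.09 and 7.25 TPM and then 0. Matrix genes fell in 19 of 34, and in 21 adjusted over the list alone, with Col3a1 from 3175 ± 176 TPM (SD, n = 2) to 445 ± 52.3 TPM (SD, n = 2), Col1a1 from 3303 ± 325 TPM (SD, n = 2) to 509 ± 52.1 TPM (SD, n = 2), and Fbln2 by -2.72 ± 0.295. Camera gave matrix genes an adjusted p = 1.15e-11, or adjusted p = 0.056 with an estimated correlation. Of 20 NF-kB genes 6 fell and 1 rose, the same adjusted over the list alone. Il6 went from 18.5 and 20 TPM to 0 and Ptgs2 changed by -3.08 ± 0.56 (camera adjusted p = 0.00794, or adjusted p = 0.113 with an estimated correlation). Of 14 smooth muscle genes 5 fell, 5 adjusted over the list alone, led by Ccn1 at -3.71 ± 0.266 and Ccn2 at -2.11 ± 0.547 (camera adjusted p = 0.0324, or adjusted p = 0.366 with an estimated correlation). Of 16 bHLH inhibitor and Notch genes 5 fell, 5 adjusted over the list alone, with Hes1 at -3.53 ± 0.571 and Bhlhe40 at -2.84 ± 0.445 (camera adjusted p = 0.00628, or adjusted p = 0.056 with an estimated correlation). Of 31 interferon genes 4 rose and 0 fell, and 6 rose and 1 fell adjusted over the list alone, with Isg15 at 1.71 ± 0.357 (camera adjusted p = 2.43e-05, or adjusted p = 0.056 with an estimated correlation). Camera did not call cell cycle exit (adjusted p = 0.749), where Btg2 fell by 2.95 and Gadd45a rose by 1.25. Nor did it call p53 targets (adjusted p = 0.173), where Mdm2 fell by 1.47, or cholesterol synthesis (adjusted p = 0.813), where Sqle fell by 1.69. Tubb3, a neuron marker, was at 1.43 and 1.04 TPM and then 0. Psd was at 25.8 and 25.6 TPM and Pcdhga6 at 12.1 and 18.9 TPM untreated and both at 0 with MyoD. In clone 2 their replicates also parted, Psd at 39.2 and 0 TPM with the plasmid and 9.76 and 0 TPM with both and Pcdhga6 at 13.9 and 0 TPM and 0 and 6.56 TPM, so these zeros are uncertain. Gpc6, a cell-surface proteoglycan, changed by -4.14 ± 0.706. Id1 and Mef2c gave -0.24 and -0.82 without passing.

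In clone 2 limma called 1731 genes, 234 higher and 1497 lower, while the median of all genes shifted by -0.305. FPKM gave 891 higher and 550 lower, and median-of-ratios scaling 196 higher and 181 lower. The total ran from 0 with only these groups in the fit, which leaves 2 libraries a side, to 2223 with reference-named transcripts only.

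**Figure D3:**
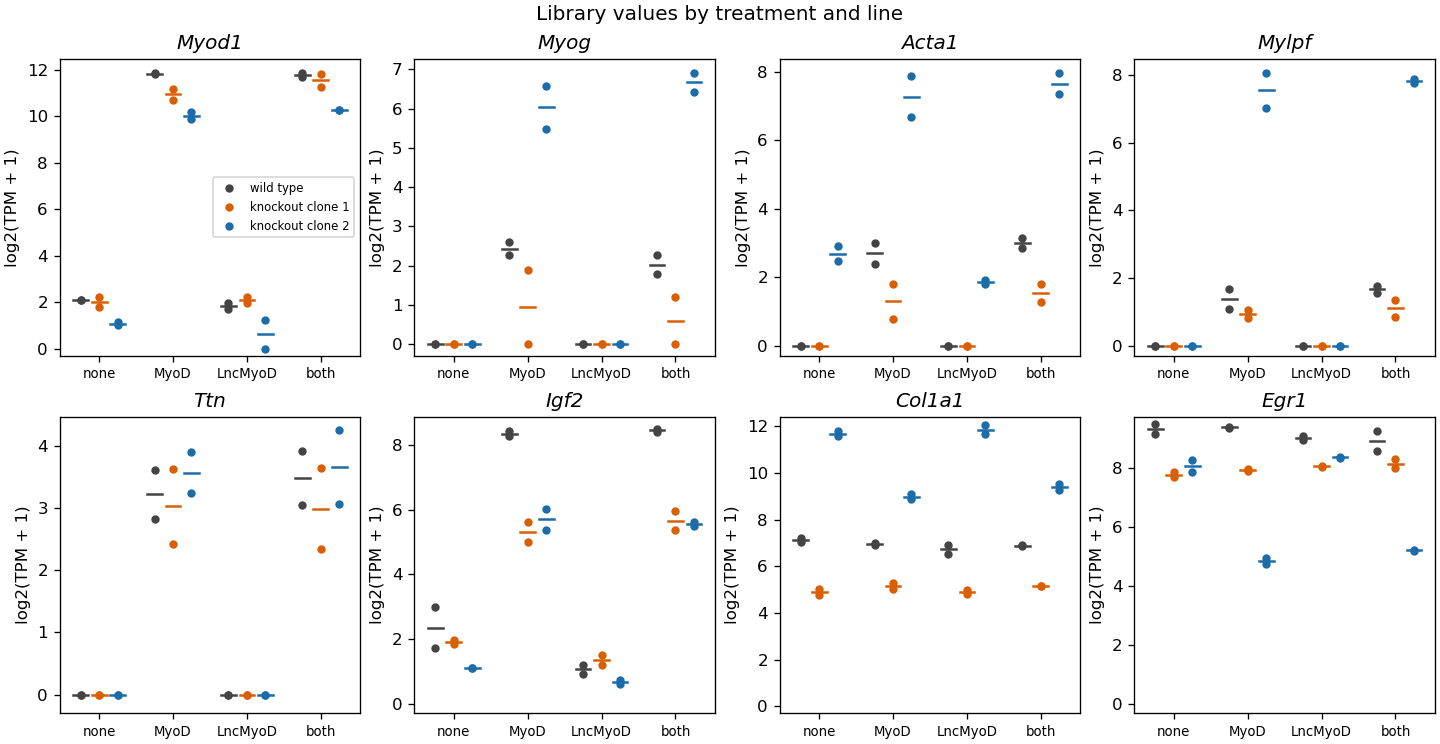
Level of 8 genes on a log2(TPM + 1) axis by treatment, with 1 point per library, a bar at the mean of the 2 libraries and colours for the lines. Myod1 rises in every line given MyoD, and Myog and Acta1 reach their highest values in clone 2, with MyoD or with both.

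Across lines, 4 genes rose in both wild type and clone 1 (H19, Igf2, Myod1 and Ttn), where 0.019 would overlap between independent lists of those sizes. Wild type and clone 2 shared 8 risen genes (0.222 if independent) and clone 1 and clone 2 shared 5 (0.262). Those 4 genes rose in all 3 lines.

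The response to MyoD differed between knockout and wild type in few genes, and in most of them the clones did not move together. Mylpf, at 0 in the untreated libraries of all 3 lines, was at 1.13 and 2.2 TPM with MyoD in wild type, 1.09 and 0.778 TPM in clone 1 and 267 and 129 TPM in clone 2 (limma adjusted p of the difference 0.0196). The immediate early gene Egr1 (chromosome 18, 34859823 to 34864984) gave -1.58 ± 0.257, with 0.11 in clone 1 and -3.27 in clone 2, and the matrix signalling gene Ccn1 gave -2.04 ± 0.326, with -0.35 in clone 1 and -3.74 in clone 2. The other calls, chosen after their values were seen, were Gm12338 at 2.95 ± 0.441, Gm10143 at -2.22 ± 0.357, Gm49394 and Gm6061. Gm49394 was at 0 and 0.658 TPM untreated and 19.6 and 16 TPM with MyoD in wild type, and at 0 in all these clone 2 libraries. Gm6061 was at 359 and 196 TPM in untreated clone 2, and listed at 0 there with MyoD and in wild type and clone 1. Gm12338 and Gm6061 are annotated as pseudogenes, Gm10143 as antisense and Gm49394 overlaps Igf2, so reads could be split with other genes and these are uncertain. Of the 8 markers fixed beforehand 0 passed (smallest limma adjusted p = 0.142). Col1a1 gave 0.44 in clone 1 and -2.52 in clone 2, Id1 0.44 in clone 1 and -0.07 in clone 2 and Mki67 -0.18 in clone 1 and -1.14 in clone 2. Myog with MyoD was at 5.05 and 3.82 TPM in wild type, 0 and 2.69 TPM in clone 1 and 95.2 and 43.9 TPM in clone 2.

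Sarcomere genes stood higher in the knockout response (1 of 32 over all genes, 2 adjusted over the list alone, median 0.614, camera adjusted p = 3.64e-07). The median was 1.22 in clone 2 (camera adjusted p = 5.18e-17) and -0.197 in clone 1 (adjusted p = 0.121). Excitation-contraction coupling genes gave 0 calls over all genes and 0 adjusted over the list alone, with a median of 0.512 (camera adjusted p = 0.00138), 1.07 in clone 2 and -0.0399 in clone 1, and -0.31 pooled with exon coverage. Immediate early genes stood lower (1 of 16 over all genes, 9 adjusted over the list alone, median -1.17, camera adjusted p = 5.51e-13), at -2.42 in clone 2 and 0.167 in clone 1. In clone 1 cell cycle, endoplasmic reticulum stress and matrix medians were 0.09, 0.07 and 0.04. Camera also placed 4 lists lower over the mean of the clones. These were cell cycle (adjusted p = 0.0113, or adjusted p = 0.208 with an estimated correlation) and endoplasmic reticulum stress genes (adjusted p = 0.00304, or adjusted p = 0.208 with an estimated correlation), with 0 members called over all genes and 0 adjusted over the list alone. The others were matrix genes with 0 of 34 over all genes and 8 adjusted over the list alone (adjusted p = 1.39e-06, or adjusted p = 0.252 with an estimated correlation), and smooth muscle genes with 1 of 14 and 2 adjusted over the list alone (adjusted p = 0.0248, or adjusted p = 0.347 with an estimated correlation).

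For this difference limma called 7 genes, 2 higher and 5 lower, with a median shift of -0.135 over all genes. Clone 1 against wild type gave 0 calls by limma with 955 genes at an unadjusted p under 0.05, or 21 when clone 2 was left out of the fit, and clone 2 against wild type gave 403, 56 higher and 347 lower. Median-of-ratios scaling brought these to 32 in clone 1, 20 higher and 12 lower, and 67 in clone 2, 32 higher and 35 lower. The count was 1 without untreated wild type replicate 1, untreated clone 1 replicate 2 or MyoD wild type replicate 2. It was 14 without untreated clone 2 replicate 1 or MyoD clone 1 replicate 2, 22 without untreated clone 2 replicate 2 and 28 without MyoD clone 2 replicate 2, and other settings for the mean of the clones ran from 0 to 100.

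**Figure D4:**
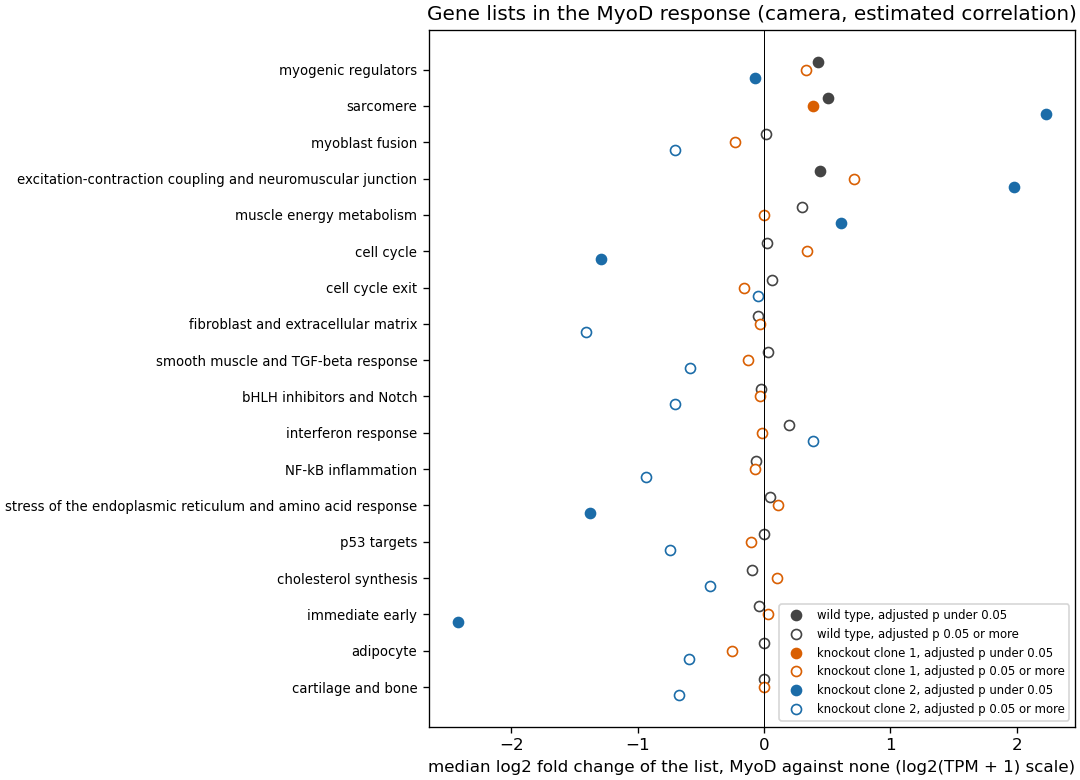
Median log2 change of each tested gene list with MyoD against none (horizontal axis) in wild type, clone 1 and clone 2, with filled points where camera gave an adjusted p under 0.05 with an estimated correlation and open points otherwise. Sarcomere genes lie at 0.507, 0.390 and 2.23 in the 3 lines and immediate early genes at -2.42 in clone 2.

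Untreated knockout cells differed from wild type, and the mean of the clones was led by clone 2. Cdkn2b, an inhibitor of cell cycle kinases (chromosome 4, 89306299 to 89311039), was listed at 0 in wild type, 3.29 and 3.28 TPM in clone 1 and 105 and 98 TPM in clone 2, and Esm1, a secreted proteoglycan, at 0, 3.98 and 7.67 TPM and 37.2 and 36.5 TPM. Lcn2, an iron-trapping protein of inflammation, rose by 3.78 ± 0.301 (SE) from 2.66 ± 1.28 TPM (SD, n = 2) (4.02 in clone 1 and 3.54 in clone 2). Aga, Lamtor5, Ing4, Plin2 and Sumo3 rose by 3.61 to 3.93 as a mean of the clones, but by 0.83 to 1.14 in clone 1 alone, where none of them passed, and by 6.24 to 6.83 in clone 2. Lower in both clones were Ly6e, a membrane-anchored protein (-4.72 in clone 1 and -3.64 in clone 2), Wnk4, a kinase of salt transport (-3.30 in clone 1 and -2.95 in clone 2), the class I antigen gene H2-Q4 (-3.14 in clone 1 and -4.30 in clone 2) and Camk2a (-2.07 in clone 1 and -4.29 in clone 2). Nxf3 was listed at 9.86 and 6.98 TPM in wild type and at 0 in both clones, and the potassium channel gene Kcnn3 at 9.9 and 17.9 TPM, 0.63 and 2.75 TPM in clone 1 and 0 in clone 2. Rn7s1 and Rn7s2, near-identical signal recognition particle RNAs whose reads could be split, gave -3.19 and -3.15. Wnk4 gave 1.34 and the matrix gene Thbs2 (here -3.04) gave 2.48 with reference-named transcripts only. Myod1 itself did not pass (-0.53 ± 0.274, with -0.06 in clone 1 and -1.0 in clone 2).

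By list, genes that rose over all genes, with those adjusted over the list alone in second place, numbered 13 and 14 of 16 for endoplasmic reticulum stress (with Hspa5 at -0.39 in clone 1 and 6.13 in clone 2), 13 and 13 of 20 for NF-kB (Cxcl5 at 0.83 in clone 1 and 4.91 in clone 2), 11 and 11 of 17 for p53 targets (Plk2 at 0.54 in clone 1 and 5.40 in clone 2), and 7 and 7 of 10 for cell cycle exit (Btg1 at 0.08 in clone 1 and 6.29 in clone 2). They numbered 16 and 16 of 37 for cell cycle, 13 and 13 of 34 for matrix with 2 lower, 10 and 11 of 31 for interferon, 8 and 8 of 16 for immediate early with 3 lower, 7 and 7 of 14 for smooth muscle with 1 lower, 7 and 7 of 19 for cholesterol synthesis, and 6 and 6 of 16 for bHLH inhibitors. Adipocyte and cartilage genes rose in 4 of 7 and 4 of 9, over all genes and adjusted over the list alone, muscle energy genes in 4 of 15, myogenic regulators in 3 of 16, and the macrophage markers Cd14 and Lyz2 in 2 of 3. Hspa5, Atf4, Id1, Junb, Klf6, Cdc20, Rrm2, Bst2, Phkg1 and S100a4 had negative values in clone 1 and positive values in clone 2, with S100a4 at -1.34 in clone 1 and 7.01 in clone 2. Of all 17886 genes 5478 rose as a mean of the clones, a share that some of these lists did not exceed. Clone 2, which led these groups, is also the line with 2.68% to 7.89% of TPM in the ribosomal RNA window. The endoplasmic reticulum stress median was 1.76 over the clones but -0.48 in clone 1 alone. Camera called endoplasmic reticulum stress, cell cycle exit, NF-kB and p53 targets (adjusted p = 0.00043, 0.00125, 0.0013 and 0.031). With an estimated correlation these gave adjusted p = 0.134, 0.0974, 0.134 and 0.286 in that order. Camera placed sarcomere genes below the other genes (adjusted p = 0.0468, or adjusted p = 0.166 with an estimated correlation). Their median was 0 and their mean 0.25, with 2 of 32 risen over all genes and 2 adjusted over the list alone. The other 13 lists were not called (adjusted p from 0.102 to 0.921).

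Without treatment limma called 5901 genes, 5478 higher and 423 lower, with a median shift of 0.618. Clone 1 gave 845 calls, 21 higher and 824 lower, at a median shift of -0.239, and clone 2 gave 10589, 10189 higher and 400 lower, at 1.53. Median-of-ratios scaling gave 1101 higher and 1322 lower for the mean of the clones, 89 and 213 in clone 1, and 2907 and 2134 in clone 2. Re-scaling over nuclear named genes, chosen after seeing the data, gave 73 and 97 in clone 1 and 3529 and 1478 in clone 2.

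With MyoD the difference of the knockout lines from wild type was again led by clone 2. The complement gene C4b rose by 4.43 ± 0.413 (SE) from 0.351 ± 0.496 TPM (SD, n = 2) (3.72 in clone 1 and 5.14 in clone 2). Cdkn2b was at 0 in wild type, 4.38 and 3.69 TPM in clone 1 and 53.1 and 53.1 TPM in clone 2, and Esm1 at 0, 4.57 and 4.09 TPM and 36.3 and 21.2 TPM. Cdo1, which breaks down cysteine, Spry2, a brake on growth factor signalling, Rida and Dpysl2 rose by 4.29, 3.88, 3.52 and 3.97 as a mean of the clones. None of these 4 passed in clone 1 taken alone, where Cdo1 gave 0.91 against 7.68 in clone 2. Dpysl2 gave -1.02 with reference-named transcripts only. Ly6e (-4.62 in clone 1 and -4.25 in clone 2), the matrix gene Thbs2 (-3.99 in clone 1 and -4.32 in clone 2), Ch25h, which makes 25-hydroxycholesterol (-4.03 in clone 1 and -3.19 in clone 2), Camk2a (-2.03 in clone 1 and -4.91 in clone 2), C1qtnf1 (-2.22 in clone 1 and -4.59 in clone 2), Wnk4 (-3.49 in clone 1 and -3.02 in clone 2) and Nhsl1 (-2.87 in clone 1 and -3.61 in clone 2) were lower in both clones, though with reference-named transcripts only Thbs2 gave 0.99 and Wnk4 0.76. Lars2 rose by 11.87 ± 3.54 and the ribosomal RNA gene CT010467.1 fell by 3.55, but both take reads of ribosomal type and Lars2 jumped between replicates (72530 and 15340 TPM in clone 1), so they are uncertain. Myod1 was lower (-1.35 ± 0.274, -0.89 in clone 1 and -1.81 in clone 2).

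Some muscle genes parted between the clones, as did genes in general, and 4570 of all 17886 genes rose as a mean. Sarcomere genes rose in 9 of 32 over all genes and 9 adjusted over the list alone, with Mylpf at -0.44 in clone 1 and 6.16 in clone 2, Tnnc2 at 0 and 1.5 TPM in wild type, 0 in clone 1 and 230.1 and 97.3 TPM in clone 2, and Acta1 at -1.40 in clone 1 and 4.58 in clone 2. Excitation-contraction coupling genes rose in 5 of 17 and 5 adjusted over the list alone (Rapsn at 0.92 in clone 1 and 4.15 in clone 2), muscle energy genes in 4 of 15 and 4 (Ldhb at -0.82 in clone 1 and 5.67 in clone 2), and fusion genes in 2 of 15 with 1 lower, the same adjusted over the list alone. Camera called none of these 4 lists (adjusted p = 0.427, 0.849, 0.358 and 0.0975). Ckm was at 0 in both wild type and clone 1 and at 10.5 and 4.64 TPM in clone 2. Immediate early genes fell in 6 of 16 and rose in 3, the same adjusted over the list alone, with Egr1 at -1.44 in clone 1 and -4.53 in clone 2 and Nr4a1 at -1.94 in clone 1 and -4.28 in clone 2 (camera adjusted p = 0.0137, or adjusted p = 0.522 with an estimated correlation). Matrix genes fell in 7 of 34 and rose in 5, also 7 and 5 adjusted over the list alone, and camera placed them lower (adjusted p = 0.0277, or adjusted p = 0.529 with an estimated correlation) while the median was 0.184 and the mean -0.00113. Higher lists by camera were cell cycle exit, NF-kB and endoplasmic reticulum stress, with 6 of 10, 8 of 20 and 8 of 16 risen. Camera gave adjusted p = 0.0277, 0.03 and 0.03, or adjusted p = 0.484, 0.522 and 0.522 with an estimated correlation. In clone 1 alone cell cycle exit and endoplasmic reticulum stress had medians of -0.48 and -0.29. The remaining lists were not called (adjusted p from 0.243 to 0.92), with 11 of 31 interferon, 9 of 19 cholesterol synthesis and 8 of 17 p53 target genes risen, the same adjusted over the list alone. Id1 was at 0.30 in clone 1 and 5.84 in clone 2, Col1a1 at -1.79 in clone 1 and 2.03 in clone 2 and Myog at -1.49 in clone 1 and 3.61 in clone 2. Id1 passed as a mean, and Col1a1, which gave -0.67 with median-of-ratios scaling, and Myog did not.

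With MyoD limma called 5243 genes, 4570 higher and 673 lower, with a median shift of 0.45. Clone 1 gave 1059, 79 higher and 980 lower, at a median shift of -0.187, and clone 2 gave 9083, 8356 higher and 727 lower, at 1.09. Median-of-ratios scaling gave 1498 higher and 1523 lower, and re-scaling over nuclear named genes 965 higher and 1707 lower. With median-of-ratios scaling clone 1 gave 210 higher and 399 lower and clone 2 3464 and 2337.

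The LncMyoD plasmid given alone changed few genes. In wild type limma called 0 genes, with 974 at an unadjusted p under 0.05 and a median shift of -0.123, and voom weights called 20. It was 2 without untreated wild type replicate 2, 1 without plasmid wild type replicate 2 and 0 without either of the other libraries. Matrix genes stood lower by camera (median -0.311, adjusted p = 0.0324, or adjusted p = 0.698 with an estimated correlation), as did immediate early genes (median -0.492, adjusted p = 0.00488, or adjusted p = 0.396 with an estimated correlation), with 0 members called over all genes or adjusted over the list alone. The ribosomal RNA window held 55.6% and 57.5% of TPM untreated and 62.6% and 69.2% with the plasmid. The matrix median was 0.08 with median-of-ratios scaling and 0.20 with re-scaling over nuclear genes. In the knockout lines Kctd12, a receptor-associated protein gene (chromosome 14, 102976581 to 102982637), was at 39.2 and 33.5 TPM in untreated clone 2 and listed at 0 there with the plasmid (limma adjusted p = 2.26e-05). It was at 0.0573 and 0.266 TPM and then 0.0156 and 0 TPM in clone 1. In clone 2 given MyoD it was at 20.3 and 22.6 TPM without and 18.3 and 25.9 TPM with the plasmid. The noncoding gene Gm26945, chosen after its values were seen, rose by 1.16 ± 0.177 (SE), with 3.84 and 4.43 TPM in clone 2 and 0 and 0.492 TPM in clone 1 with the plasmid. Of the 18 tested lists camera called 0 in the knockout lines (adjusted p from 0.119 to 0.984). Myod1 gave -0.22 ± 0.316 in wild type and -0.19 ± 0.224 in the knockout lines, and did not pass in either. By limma 2 genes were called in the knockout lines, 857 at an unadjusted p under 0.05. Taken alone, clone 1 gave 0, 851 at an unadjusted p under 0.05, and clone 2 gave 64. The count of 2 was 18 and 49 without untreated clone 2 replicate 1 or 2, 27 and 19 without plasmid clone 2 replicate 1 or 2, 4 without untreated clone 1 replicate 2 and 1 without plasmid clone 1 replicate 2.

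With the plasmid added to MyoD some genes were called in the knockout lines, and these did not include the muscle markers. Pfkfb3, which drives glycolysis (chromosome 2, 11471433 to 11554077), rose by 2.15 ± 0.33 (SE), with 3.13 in clone 1 and 1.17 in clone 2, and the transcription factor gene Pou2f1 by 1.75 ± 0.265, with 2.46 in clone 1 and 1.03 in clone 2. Ch25h (1.60 in clone 1 and 2.16 in clone 2), Stom (1.97 in clone 1 and 1.00 in clone 2), Ibtk (2.14 in clone 1 and 0.48 in clone 2) and the splicing gene Snrnp40 (2.03 in clone 1 and 0.52 in clone 2) also rose. Metap1, listed at 0 in clone 1 with MyoD, was at 3.4 and 9.89 TPM there with the plasmid and went from 8.04 and 3.21 TPM to 10.9 and 10.1 TPM in clone 2 (limma adjusted p = 0.0317). Ifih1, a viral RNA sensor, was at 0 and then 3.09 and 4.05 TPM in clone 1 and at 3.76 and 4.67 TPM and then 7.86 and 6.56 TPM in clone 2 (adjusted p = 0.0462). Lower were Ankle2 (-2.52 in clone 1 and -0.93 in clone 2, and 0 as a mean with reference-named transcripts only), Trerf1 (-0.20 in clone 1 and -3.08 in clone 2, and 0.13 as a mean with exon coverage and 0.95 with reference-named transcripts only) and Txnrd1, a redox enzyme (-1.87 in clone 1 and -0.76 in clone 2). Of 31 interferon genes 1, Ifih1, rose, also 1 adjusted over the list alone. Of the 8 markers 0 passed, with mean changes from -0.36 to 0.41, among them Myog at 0.15 ± 0.366 and Acta1 at 0.31 ± 0.291. Camera placed matrix genes (adjusted p = 0.00484) and NF-kB genes (adjusted p = 0.0059) higher, each with adjusted p = 0.587 with an estimated correlation and 0 members called over all genes or adjusted over the list alone. In wild type the T cell receptor segment Traj6 went from 1.74 and 1.63 TPM to 0 and was the 1 call, chosen after its values were seen (limma adjusted p = 0.0313), with 874 genes at an unadjusted p under 0.05. The count was 3 without MyoD wild type replicate 1, 5 without MyoD and plasmid wild type replicate 1 and 0 without either replicate 2, and the settings ran from 0 to 47. The 8 markers gave log2 changes from -0.41 to 0.68 in wild type (limma adjusted p = 1 for each). Camera there placed sarcomere, excitation-contraction coupling and interferon genes higher and p53 targets lower, in that order at adjusted p = 0.0122, 0.0228, 0.0122 and 0.0228. With an estimated correlation these gave adjusted p = 0.151, 0.27, 0.343 and 0.343. Over all genes or adjusted over the list alone 0 members were called.

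For the plasmid with MyoD in the knockout lines limma called 66 genes, 47 higher and 19 lower. Clone 1 gave 48 and clone 2 gave 273, but 220 and 30 with median-of-ratios scaling. The clones had 0 genes called higher in both, 0 called lower in both and 1 called in opposite directions, against 0.235 higher and 0.135 lower for independent lists. Median-of-ratios scaling gave 13 higher and 27 lower for their mean. The count without a single library ran from 26, without MyoD clone 1 replicate 1 or combined clone 1 replicate 2, to 225 without combined clone 2 replicate 1. It was 198 without MyoD clone 1 replicate 2, 151 and 137 without MyoD clone 2 replicate 1 or 2, and 121 without combined clone 2 replicate 2.

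The effect of the plasmid under MyoD differed between knockout and wild type in 3 genes by limma, 2 higher and 1 lower, with a median shift of 0.229 and 1412 genes at an unadjusted p under 0.05. The kinetochore gene Ska3 (chromosome 14, 57806561 to 57826185) was at 3.78 and 4.32 TPM with MyoD and 1.18 and 1.5 TPM with both in wild type. It was listed at 0 with MyoD in both clones, and with both at 2.46 and 2.31 TPM in clone 1 and 5.65 and 5.89 TPM in clone 2 (limma adjusted p = 0.0355). Letm2 gave a difference of 2.72 ± 0.419 (SE), with 3.03 in clone 1 and 2.42 in clone 2. The pseudogene Gm6485, chosen after its values were seen, gave -3.85 ± 0.572 and 0.01 with exon coverage, and was at 82.7 and 93.3 TPM in clone 2 with MyoD and at 0.931 and 0.619 TPM in clone 1. Of the 8 markers 0 passed, with differences from -0.58 to 0.56 (smallest limma adjusted p = 0.834). Camera placed cell cycle exit (median 0.357, adjusted p = 0.0372), matrix (0.470, adjusted p = 0.00374), NF-kB (0.593, adjusted p = 0.0224), p53 target (0.510, adjusted p = 0.0224) and immediate early genes (0.527, adjusted p = 0.0224) higher and excitation-contraction coupling genes lower (-0.132, adjusted p = 0.0309). With an estimated correlation these gave adjusted p = 0.359 for cell cycle exit, NF-kB, p53 targets and excitation-contraction coupling and adjusted p = 0.484 for the others. Adjusted over the list alone 2 cell cycle exit genes and 1 NF-kB gene rose, and over all genes 0 members of these lists passed. Taken alone, clone 1 gave 4 calls and clone 2 gave 57. Single libraries moved the count of 3 to 0 without MyoD wild type replicate 2, MyoD clone 1 replicate 1, combined wild type replicate 2, or either combined clone 2 library, to 1 without MyoD clone 2 replicate 1, to 6 without MyoD clone 1 or clone 2 replicate 2, and to 8 without combined clone 1 replicate 1.

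Over the 11 comparisons camera called 48 lists with its preset correlation, and 14 of them held with an estimated correlation. These were myogenic regulators, sarcomere and excitation-contraction coupling in wild type with MyoD, and sarcomere in clone 1. In clone 2 they were myogenic regulators (adjusted p = 0.0499 with an estimated correlation), sarcomere, excitation-contraction coupling, muscle energy metabolism, cell cycle, endoplasmic reticulum stress and immediate early genes. In the difference of the MyoD response they were sarcomere, excitation-contraction coupling (adjusted p = 0.0484 with an estimated correlation) and immediate early genes.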

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

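The tests of the ribosomal share, of a batch, of pressed low values and of the MyoD level were chosen after their results had been seen, and the tests of GC content with length and of missing transcripts before.

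Untreated clone 2 differed from wild type in 10589 genes and clone 1 in 845. Re-scaling over nuclear named genes, which keeps Lars2, left 5007 calls in clone 2 and 170 in clone 1, a ratio of 29.5. Median-of-ratios scaling left 5041 and 302, so the ribosomal RNA share does not account for the whole gap. Nor does GC content with transcript length, which explained 12% of the variance of clone 2 minus wild type and 0.414% for clone 1. Taking out their trend brought the median-of-ratios calls to 4543 and 298, a ratio of 15.2. A separate library or sequencing batch of clone 2 stays open: the labels give no batch, and its highest correlation with another line was 0.679. A biological difference of the clone, by knockout or derivation, stays open and was not tested.

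Sarcomere genes rose more with MyoD in clone 2 than in wild type, with a median difference of 1.22. More MyoD in clone 2 is argued against by Myod1 itself, at a mean of 1046 TPM in clone 2 and 3653 TPM in wild type, a ratio of 0.286. Low wild type values pressed together by the pseudocount and the scaling may account for part of it, and this stays open: with median-of-ratios values and a pseudocount of 0.1 the list stood higher at a camera adjusted p = 0.0267 (median 0.864) but at an adjusted p = 0.0898 with an estimated correlation. Whether clone 2 was a separate batch stays open here too. A greater myogenic response of this clone is a hypothesis, and clone 1 gave a median of -0.197.

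Nearly all genes called between untreated clone 1 and wild type were lower in clone 1, 824 of 845. The ribosomal RNA share may account for part of the direction, since re-scaling over nuclear named genes left 57.1% of calls lower (97 of 170). That re-scaling kept Lars2, at 46210 and 13920 TPM in wild type and 16520 and 0.764 TPM in clone 1, so it is not free of ribosomal reads. Median-of-ratios scaling left 213 of 302 lower, so whether the share accounts for all of it stays open. Of the genes called lower 8.01% (66 of 824) were listed at 0 in both clone 1 libraries. For the rest this argues against whole genes left unassembled in clone 1. It cannot see loss of some transcripts or in 1 library, which stays open. An effect of the knockout on single genes called lower stays open and was not tested.

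The response to MyoD differed between knockout and wild type, by the interaction test of limma, in 7 genes over the mean of the clones, in 0 for clone 1 (955 at an unadjusted p under 0.05) and in 403 for clone 2, 56 higher and 347 lower. With median-of-ratios scaling clone 1 gave 32 and clone 2 gave 67, 32 higher and 35 lower. For the mean the log2 differences were 2.95 for Gm12338, 2.86 for Mylpf, -1.58 for Egr1, -2.04 for Ccn1, -2.22 for Gm10143, -3.44 for Gm49394 and -4.03 for Gm6061. In clone 1 alone Gm12338, Mylpf and Egr1 had the other sign (-0.6, -0.44 and 0.11). Mylpf, Gm49394 and Gm6061 were listed at 0 in whole groups, so their values depend on the pseudocount. Lists that differed by camera, also with an estimated correlation, had medians of 0.614 for sarcomere (-0.2 in clone 1), 0.512 for excitation-contraction coupling (-0.04 in clone 1) and -1.17 for immediate early genes (0.17 in clone 1). With the preset correlation alone these were -0.572 for cell cycle (0.09 in clone 1), -0.633 for endoplasmic reticulum stress (0.07), -0.577 for matrix (0.04) and -0.4 for smooth muscle genes (-0.09). With an estimated correlation they gave adjusted p = 0.208, 0.208, 0.252 and 0.347 in that order.

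The plasmid effect under MyoD differed between knockout and wild type in 3 genes for the mean of the clones, 4 for clone 1 and 57 for clone 2. The log2 differences were 3.37 for Ska3, which was listed at 0 in both clones with MyoD, 2.72 for Letm2 and -3.85 for Gm6485. Camera called 6 lists with its preset correlation and 0 of them with an estimated correlation (adjusted p = 0.359 or 0.484). Their medians were -0.132 for excitation-contraction coupling, 0.357 for cell cycle exit, 0.47 for matrix, 0.593 for NF-kB, 0.51 for p53 targets and 0.527 for immediate early genes.

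Outside the gene table, the transcript at the LncMyoD locus was at 2.64 TPM or more in every plasmid library and in 0 of the 12 others. Other minus-strand fragments there were at 0.692 TPM in clone 1 with MyoD replicate 1 (46344918 to 46346828) and at 1.95 TPM in clone 2 with MyoD replicate 2 (46346902 to 46347339).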

How the results depend on the processing

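Re-scaling over nuclear named genes, exon coverage and fits without or with only clone 2 were chosen after seeing the data. The comparisons, lists, naming rule and other settings were fixed before. Of 250 pairs of a named gene and a comparison 188 were called, and 16 of these calls held in every setting, 37 changed sign in at least 1 and 159 were lost in at least 1. Among 48 called lists 9 held in every setting, 12 changed sign in at least 1 and 38 were lost in at least 1. With an estimated correlation 14 of the 48 held and 34 were lost, each in its direction. Median-of-ratios scaling kept 136 of the 188 gene calls and voom weights 129, quantile normalization 139, re-scaling over nuclear genes 130, exon coverage 131 and FPKM 170. A pseudocount of 0.1 kept 165, no filter 181 and library quality weights 175, while only the groups that enter a comparison kept 95. Leaving out a single library kept 915 of 1092 gene calls and 253 of 324 list calls, and changed the sign of 0 called genes and 0 called lists. The depth behind single values is unknown, so what depth limits cannot be given. For MyoD in wild type the test recovered 44% of simulated changes of 1.5 on the log2 scale and 94% of changes of 3. What limited this was not tested. Reference-named transcripts only gave no value for 6 of the 188 calls and the filter of 5 TPM none for 4.

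With the replicate number as a block in the fit, the numbers showed no pairing: over 66 pairs of groups the correlation of replicate deviations ran from -0.0428 to 0.041, and 0 pairs were above 0.1. The block kept 182 of 188 gene calls and 48 of 48 list calls. Its counts were 1 for the plasmid alone in the knockout lines, 0 for the plasmid with MyoD in wild type and 43 for the plasmid with MyoD in the knockout lines, and the others stayed within 1.5 times. These numbers are only names, and a call lost with the block is not read as a weaker effect.

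For counts that moved by over 1.5 times and values that changed sign, the cause was not tested, except that clones alone, groups alone, left-out libraries and stricter filters leave fewer samples or genes by construction. Counts are of genes called, gene values are log2 changes and list values are medians. Values of Acta1, Ckm, Jsrp1, Mylpf, Mymk, Myog, Phkg1 and Tnnc2 where a whole group is listed at 0 depend on the pseudocount and are no measure of size.

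Knockout clone 1 taken alone gave 0 for the difference in MyoD response and 0 for the plasmid alone in the knockout lines. It gave 845 and 1059 for knockout against wild type untreated and with MyoD. Acta1, Col1a1, Egr1, Gm12338, Mylpf, Myog and sarcomere genes gave -1.4, 0.44, 0.11, -0.6, -0.44, -1.49 and -0.2 for the difference in MyoD response. Excitation-contraction coupling, cell cycle, matrix, endoplasmic reticulum stress and immediate early genes gave -0.04, 0.09, 0.04, 0.07 and 0.17 there. Atf4, Bst2, Cdc20, Hspa5, Id1, Junb and Klf6 gave -0.25, -0.06, -0.91, -0.39, -0.14, -0.58 and -0.5 for untreated knockout against wild type. Phkg1, Rrm2, S100a4, sarcomere genes and endoplasmic reticulum stress genes gave -0.3, -0.3, -1.34, 0 and -0.48 there. Acta1, Acta2, Atf4, Bax, Col1a1, Hes6 and Hspa5 gave -1.4, -0.43, -0.64, -0.23, -1.79, -0.99 and -0.26 for knockout against wild type with MyoD. Ifi204, Jsrp1, Ldhb, Mylpf, Mymk, Myog and Phlda3 gave -0.02, -0.4, -0.82, -0.44, -1.03, -1.49 and -0.39 there. Pparg, S100a4, Tnnc2, cell cycle exit genes and endoplasmic reticulum stress genes gave -0.45, -1.18, -0.66, -0.48 and -0.29 there. Myod1 gave 0.08 for the plasmid alone in the knockout lines. Col1a1, Mymk and Myog gave -0.01, -0.59 and -0.35 for the plasmid with MyoD in the knockout lines. Acta1 gave -0.07 for the difference in plasmid effect. Without the clone 2 libraries in the fit, clone 1 gave counts of 21 for the differences in MyoD response and in plasmid effect. They were 623 and 771 for knockout against wild type untreated and with MyoD, and 12 and 23 for the plasmid alone and with MyoD. Gene and list values stayed the same.

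Taken alone, knockout clone 2 gave 403 for the difference in MyoD response and 57 for the difference in plasmid effect. It gave 10589 and 9083 for knockout against wild type untreated and with MyoD. For the plasmid in the knockout lines it gave 64 alone and 273 with MyoD. Id1 and Mymk gave -0.07 and 0.73 for the difference in MyoD response. Mef2c gave 0.54 for the plasmid with MyoD in the knockout lines. Mef2c and Mymk gave 0.31 and 0.46 for the difference in plasmid effect.

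A pseudocount of 0.1 gave 92 for MyoD in clone 1, 1028 for MyoD in clone 2, 3 for the difference in MyoD response, 5 for the plasmid alone in the knockout lines, 4 for the plasmid with MyoD in wild type and 8 for the difference in plasmid effect. Adipocyte genes gave 0 for MyoD in wild type. Acta1 gave -1.45 for the difference in MyoD response. Mymk gave -0.31 for the plasmid with MyoD in the knockout lines. Without a filter on low values the counts were 55 for MyoD in clone 1, 32 for the difference in MyoD response, 4 for the plasmid alone in wild type, 6 for the plasmid alone in the knockout lines, 13 for the plasmid with MyoD in wild type and 20 for the difference in plasmid effect. A filter of 5 TPM in 2 libraries, which tests fewer genes, gave 6 for MyoD in clone 1, 1 for the plasmid alone in the knockout lines, 0 for the plasmid with MyoD in wild type and 20 for the plasmid with MyoD in the knockout lines.

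FPKM in place of TPM gave 10 for MyoD in wild type, 1 for the plasmid alone in the knockout lines and 1 for the difference in plasmid effect. Id1 gave 0.35 for MyoD in clone 2. Mymk gave 0.15 for the difference in MyoD response. Myod1 and matrix genes gave 0.06 and 0.07 for the plasmid alone in wild type. Col1a1, Id1 and Myod1 gave 0.07, 0.02 and 0.08 for the plasmid with MyoD in wild type. Acta1 gave -0.13 for the difference in plasmid effect. Median-of-ratios scaling gave counts of 42 for MyoD in wild type, 216 for MyoD in clone 1, 377 for MyoD in clone 2, 13 for the difference in MyoD response, 2423 for untreated knockout against wild type and 3021 for knockout against wild type with MyoD. With that scaling counts were 8 and 7 for the plasmid alone in wild type and the knockout lines. For the plasmid with MyoD they were 12 and 40, and for the difference in plasmid effect 6. Id1 gave 0.27 for MyoD in clone 2. Col1a1, Mki67 and Mymk gave -0.67, -0.08 and -0.5 for knockout against wild type with MyoD. Myod1 and matrix genes gave 0.08 and 0.08 for the plasmid alone in wild type. Col1a1, Id1 and Myod1 gave 0.2, 0.14 and 0.21 for the plasmid with MyoD in wild type. Mymk and Myog gave -0.02 and -0.08 for the plasmid with MyoD in the knockout lines. Acta1 and Col1a1 gave -0.37 and -0.14 for the difference in plasmid effect.

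Quantile normalization gave counts of 34 for MyoD in wild type, 227 for MyoD in clone 1, 371 for MyoD in clone 2, 20 for the difference in MyoD response and 2417 for untreated knockout against wild type. Quantile counts were also 2841 for knockout against wild type with MyoD, 6 for the plasmid alone in wild type, 15 for the plasmid with MyoD in wild type, 27 for the plasmid with MyoD in the knockout lines and 6 for the difference in plasmid effect. Adipocyte genes gave 0 for MyoD in wild type. Acta1 and Myog gave -0.08 and -0.12 for the difference in MyoD response. Sarcomere genes gave 0.03 for untreated knockout against wild type. Col1a1, Mki67, Mymk and Myog gave -0.39, -0.22, -0.61 and -0.09 for knockout against wild type with MyoD. Myod1 and matrix genes gave 0.1 and -0.01 for the plasmid alone in wild type. Myod1 gave 0.04 for the plasmid alone in the knockout lines. Col1a1 and Id1 gave 0.2 and 0.13 for the plasmid with MyoD in wild type. Mymk and Myog gave -0.05 and -0.08 for the plasmid with MyoD in the knockout lines. Acta1 and Col1a1 gave -0.32 and -0.16 for the difference in plasmid effect. Re-scaling over nuclear named genes gave counts of 68 for MyoD in wild type, 567 for MyoD in clone 1, 307 for MyoD in clone 2, 20 for the difference in MyoD response and 2019 for untreated knockout against wild type. Nuclear re-scaling also gave 2672 for knockout against wild type with MyoD, 9 for the plasmid alone in wild type, 20 for the plasmid alone in the knockout lines, 47 for the plasmid with MyoD in wild type and 21 for the difference in plasmid effect. Col1a1 and Id1 gave 0.06 and 0.02 for MyoD in wild type and -0.24 and -0.13 for MyoD in clone 1. Acta1, Id1 and Myog gave -1.09, -0.13 and -0.45 for the difference in MyoD response. Col1a1, Mki67, Mymk and Myog gave -0.88, -0.41, -0.82 and -0.45 for knockout against wild type with MyoD. Myod1 and matrix genes gave 0.21 and 0.2 for the plasmid alone in wild type. Col1a1 and Myod1 gave 0 and 0.01 for the plasmid with MyoD in wild type. Mymk and Myog gave -0.2 and -0.12 for the plasmid with MyoD in the knockout lines. Acta1 gave -0.02 for the difference in plasmid effect.

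Reference-named transcripts only gave counts of 32 for MyoD in clone 1, 100 for the difference in MyoD response, 3 for the plasmid alone in wild type, 38 for the plasmid alone in the knockout lines and 7 for the plasmid with MyoD in wild type. They also gave 134 for the plasmid with MyoD in the knockout lines and 10 for the difference in plasmid effect. Mki67 and cholesterol synthesis genes gave -0.91 and 0 for MyoD in wild type. Mef2c and Numa1 gave -0.5 and -1.71 for MyoD in clone 1. Mki67 gave 0.15 for the difference in MyoD response. Thbs2 and Wnk4 gave 2.48 and 1.34 for untreated knockout against wild type. Dpysl2, Mymk, Thbs2 and Wnk4 gave -1.02, -0.29, 0.99 and 0.76 for knockout against wild type with MyoD. Acta1, Ankle2, Mef2c, Myog and Trerf1 gave -0.26, 0, 0.27, -0.15 and 0.95 for the plasmid with MyoD in the knockout lines. Acta1, Mef2c and Mymk gave -0.6, 0.15 and 0.14 for the difference in plasmid effect. Exon coverage per gene gave counts of 74 for MyoD in wild type, 790 for MyoD in clone 1, 713 for MyoD in clone 2, 38 for the difference in MyoD response and 2687 for untreated knockout against wild type. Exon coverage also gave 3 for the plasmid alone in wild type, 54 for the plasmid alone in the knockout lines, 46 for the plasmid with MyoD in wild type, 107 for the plasmid with MyoD in the knockout lines and 17 for the difference in plasmid effect. Lrch1, Mki67, adipocyte genes and cartilage and bone genes gave 0.26, -0.16, 0.1 and 0 for MyoD in wild type. Col1a1, Mki67 and Numa1 gave -0.01, 0.84 and -0.26 for MyoD in clone 1. Acta1, Myog and excitation-contraction coupling genes gave -1.25, -0.53 and -0.31 for the difference in MyoD response. Col1a1, Mki67, Mymk and Myog gave -0.65, -1.46, -1.34 and -0.53 for knockout against wild type with MyoD. Myod1 gave 0.01 for the plasmid alone in wild type. Col1a1, Id1, Myod1 and p53 targets gave 0.2, 0.13, 0.2 and -0.01 for the plasmid with MyoD in wild type. Mef2c, Myog and Trerf1 gave 0.14, -0.26 and 0.13 for the plasmid with MyoD in the knockout lines. Acta1, Col1a1, Gm6485, Mki67 and Myog gave -0.53, -0.04, 0.01, 0.12 and -0.01 for the difference in plasmid effect.

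Voom weights gave counts of 39 for MyoD in wild type, 58 for MyoD in clone 1, 3049 for untreated knockout against wild type, 20 for the plasmid alone in wild type and 39 for the plasmid alone in the knockout lines. Voom also gave 24 for the plasmid with MyoD in wild type, 132 for the plasmid with MyoD in the knockout lines and 10 for the difference in plasmid effect. Mki67 and adipocyte genes gave -0.12 and -0.1 for MyoD in wild type. Mki67 and Numa1 gave 1.06 and -0.01 for MyoD in clone 1. Id1 gave 0.09 for MyoD in clone 2. Acta1 and Myog gave -2.9 and -0.16 for the difference in MyoD response. Mki67 and Mymk gave -1.13 and -0.05 for knockout against wild type with MyoD. Myod1 and matrix genes gave 0.06 and -0.03 for the plasmid alone in wild type. Mymk and Myog gave -0.49 and -0.27 for the plasmid with MyoD in the knockout lines. Acta1 and Mki67 gave -0.24 and 0.91 for the difference in plasmid effect. Library quality weights gave 35 for MyoD in wild type, 20 for the difference in MyoD response, 2 for the plasmid alone in wild type, 5 for the plasmid alone in the knockout lines, 30 for the plasmid with MyoD in wild type and 20 for the plasmid with MyoD in the knockout lines.

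With only the groups of a comparison MyoD gave 1 in wild type and 0 in each clone. That fit leaves few residual degrees of freedom and drops other groups at 0. The difference in MyoD response and the plasmid alone in the knockout lines also gave 0. Counts were 0 and 23 for the plasmid with MyoD in wild type and the knockout lines and 9 for the difference in plasmid effect. A fit without the clone 2 libraries gave 43 for MyoD in wild type, 14 for the plasmid alone in wild type and 21 for the plasmid with MyoD in wild type. Adipocyte genes gave 0 for MyoD in wild type. A fit of the clone 2 libraries alone gave 912 for MyoD in clone 2.

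With each library left out in turn, where a lone library is taken to vary like the other groups, counts ran from 6 to 12 for MyoD in wild type, 1 to 28 for the difference in MyoD response, 0 to 2 for the plasmid alone in wild type and 6 to 497 for MyoD in clone 1. Further ranges were 1 to 49 for the plasmid alone in the knockout lines, 0 to 5 for the plasmid with MyoD in wild type, 0 to 8 for the difference in plasmid effect and 26 to 225 for the plasmid with MyoD in the knockout lines. Id1 ranged from -0.35 to 0.03, cholesterol synthesis genes from -0.29 to -0.02, adipocyte genes from 0 to 0 and cartilage and bone genes from 0 to 0 for MyoD in wild type. Acta1 ranged from -0.05 to 0.56, Id1 from -0.01 to 0.37 and Mymk from -0.57 to 0.27 for the difference in MyoD response. Mki67 ranged from -0.25 to 0.11 for MyoD in clone 1. Myod1 ranged from -0.5 to 0.13 for the plasmid alone in the knockout lines. Mymk ranged from -0.15 to 0.7 for knockout against wild type with MyoD. Id1 ranged from -0.22 to 0.08, Mef2c from -0.53 to 0.98 and Myod1 from -0.15 to 0 for the plasmid with MyoD in wild type. Acta1 ranged from -0.3 to 0.31, Ckm from -0.39 to 0.12, Mef2c from -1.34 to 0.17 and Mki67 from -0.72 to 0.18 for the difference in plasmid effect. Mymk ranged from -0.83 to 0.02 there. Ckm ranged from -0.39 to 0.12, Mki67 from -0.04 to 0.86, Mymk from -0.15 to 0.7 and Myog from -0.32 to 0.62 for the plasmid with MyoD in the knockout lines.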

Other observations

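No test was added for this part, which gives values only, chosen after they were seen. The imprinted pair that rose with MyoD was also high in the groups given MyoD and the plasmid, a comparison with untreated cells that was not tested. Igf2 was at 359.7 and 342 TPM in wild type, 40.6 and 61 TPM in clone 1 and 48.8 and 44.2 TPM in clone 2, and H19 at 24.3 and 18.5 TPM, 8.07 and 13.5 TPM and 75.9 and 98.7 TPM in the same order.

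Between replicates Actb was at 313 and 4619 TPM in untreated clone 2 and at 5622 and 60.2 TPM in clone 2 with both.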
